A study of Papio hamadryas with 11 samples.

How the data were processed

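Total RNA from the livers of 11 near-term baboon fetuses (Papio hamadryas, 165 days, 0.9 of gestation) was hybridised to human Illumina expression BeadChips, 1 array per fetus. 6 fetuses came from control mothers and 5 from obese mothers. The control arrays are called CON1 to CON6 and the maternal obese arrays MO1 to MO5. CON1, CON2, CON3, MO1, MO2 and MO3 were from female fetuses and the other 5 from males, per the labels. The arrays lay on a pair of slides. Slide 1 held CON1 to CON4, and slide 2 held CON5, CON6 and all 5 maternal obese arrays. Replicate numbers only name arrays and pair none of them.

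RNA was extracted with TRI Reagent and a column clean-up and amplified to labelled cRNA with an Illumina Total Prep kit, per the labels' protocols. The deposited table gives, for each of 48803 probes and each array, a probe intensity on a linear scale and a detection p-value. The submitters' processing notes name GenomeStudio and Partek, without saying what each was used for, and their versions are not given in the sources used here. The deposited series matrix holds log2 values. Set against the intensities of the same arrays, they were the log2 of those intensities, with a largest difference of 5.00e-09, so they were neither background-corrected nor normalized between arrays. Their scale, centring and direction were thereby settled, and no column of values remained without a sample (0 unmatched columns). Because the probes were designed on human sequence, a mismatch to baboon RNA can lower a probe's signal. Levels of different probes were therefore compared only to choose the probe of a gene and the markers to name. No baboon sequence was at hand, so whether a mismatch acts alike on all 11 arrays was not checked.

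The intensities were normalized with limma 3.58.1 in R 4.3.3. The function neqc applied a normexp background correction, with the negative-control distribution inferred from the detection p-values and an offset of 16, then quantile normalization, and gave log2 values. Probes with a detection p under 0.05 on at least 5 arrays were kept, which left 11475 of the 48803. The platform annotation gave 1 gene symbol to 28098 probes, several to 13, and did not list 20692. Where several kept probes shared a symbol, the probe with the highest mean over the 11 arrays stood for the gene. This gave 10173 features, 8043 of them with 1 gene symbol and 2130 without, which were tested but not named. Probes of near-identical family members (metallothioneins, GSTM, UGT1A, RPS4Y and globin genes) may bind more than 1 transcript, and their values are uncertain in that respect.

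Differences are maternal obese minus control, or female minus male, on the log2 scale. They were tested with limma's lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The first comparison set 5 maternal obese against 6 control arrays with no covariate, as the series design names none. The contrasts within females, within males and between those contrasts (the interaction of sex and maternal obesity) came from a fit of 4 group means. Female against male was tested with condition as a covariate. SD is the spread between arrays of a group, and SE is limma's moderated standard error. The p-values of the gene tests measure the spread between these fetal samples, and the number of arrays limits the precision. KCTD7, not detected on any control female array, and SQLE, LSS and ELOVL6, not detected on any maternal obese female array, have only a bound there, formed from the lowest detected signal of each array.

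38 gene lists, 28 of pathways and 10 of cell type markers, held 1446 genes, of which 873 were measured. A list's shift relative to all other genes was tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the 38 lists. At this preset value the camera p-value rests on the spread of the statistics between genes, not between fetuses. A list needed at least 5 measured members. The tests were repeated with a correlation estimated from the data and with fry, which tests whether the genes of a list move one way on balance without reference to other genes. A list's score on an array is the mean over its members of the difference from each gene's mean over the 11 arrays. Scores were compared with two-sided exact permutation tests over the 462 splits of the arrays into 6 and 5, the 21 splits of slide 2 into 2 and 5, or, for the interaction, 200 reassignments of the sexes within each condition.

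The groups, the gene tests of all 5 comparisons, the list test of maternal obese against control, the lists, other settings to try and the rule for naming genes were fixed before the data were examined. The list tests within females, within males, for the interaction and for female against male were added after. The rule took up to 12 genes per direction past the threshold. Where fewer passed, it took the 5 genes per direction with the smallest p, which are given with values only. It further took up to 4 members with the smallest p from each list described, 2 markers with the highest level from each cell type list described, 5 genes per direction for the sex-specific and sex contrasts, and a set of X- and Y-linked transcripts as a check of the sex labels. Which lists to describe in detail was decided after the values were seen, as was the naming of MT1B per array, of the genes that pass when adjusted over the list alone, and of GAS2 in the comparison of all arrays.

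The other settings chosen beforehand were quantile normalization without background correction, scaling each array to a common median after background correction, the series matrix values, no filter on dim probes, detection p under 0.01 on all 11 arrays, all probes tested separately, slide as covariate or random block, slide 2 alone, the males of slide 2 alone, sex or sex and slide as covariates, array weights, a trended and robust prior, and leaving out each array in turn. Chosen after seeing the data were the fits without CON3 and CON4, and the other settings for the gene lists in the interaction, within females, within males and in female against male.

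The tests were tested on simulated data with 200 of 10173 genes changed. At log2 sizes of 0.5, 1 and 2, the comparison of all 11 arrays recovered 10%, 82.5% and 97% of them, the female contrast 0%, 58% and 95%, the male contrast 0%, 48.5% and 92%, the interaction 0%, 0.5% and 82%, and female against male 13.5%, 84.5% and 96.5%. A simulated shift of -0.25 in the TCA cycle list was found in 20 of 20 simulations, with 1 of 740 tests of the other lists called. These simulations hold independent genes and no slide effect.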

Results

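Transcript levels were measured in the livers of 11 near-term baboon fetuses, 6 from control mothers (CON1 to CON6) and 5 from obese mothers (MO1 to MO5), with 1 human expression array per fetus. The control group held 3 females and 3 males and the maternal obese group 3 females and 2 males. Of 48803 probes, 10131 (MO4) to 13065 (CON4) were detected per array, which is 20.8% to 26.8%. Median intensities were 62 to 65.6 on the 4 arrays of slide 1 and 69.7 to 80.3 on the 7 arrays of slide 2, and the medians of the deposited log2 values ran from 5.95 to 6.33. After normalization, arrays correlated with each other at 0.930 to 0.982 across features, with a median of 0.969 within a slide and 0.953 between slides. No array repeated another.

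The first principal component held 31.0% of the variance and separated the slides. Slide 1 arrays lay between -36.4 and -16.0 and slide 2 arrays between 3.13 and 25.3 (exact permutation p = 0.00303, the smallest of 330 splits). Condition did not separate along it within slide 2 (exact permutation p = 0.667). Between the 2 control arrays of slide 2 and the 4 of slide 1, limma called 361 genes, 30 higher and 331 lower on slide 2. Both of these slide 2 controls were male and 3 of the 4 on slide 1 female, so this count mixes slide with sex. The same holds over all 11 arrays with condition as a covariate, where 849 genes were called, 297 higher and 552 lower on slide 2. Slide 1 held only controls, so a fit with slide as a covariate rests on CON5 and CON6 against the 5 maternal obese arrays of slide 2.

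**Figure D1:**
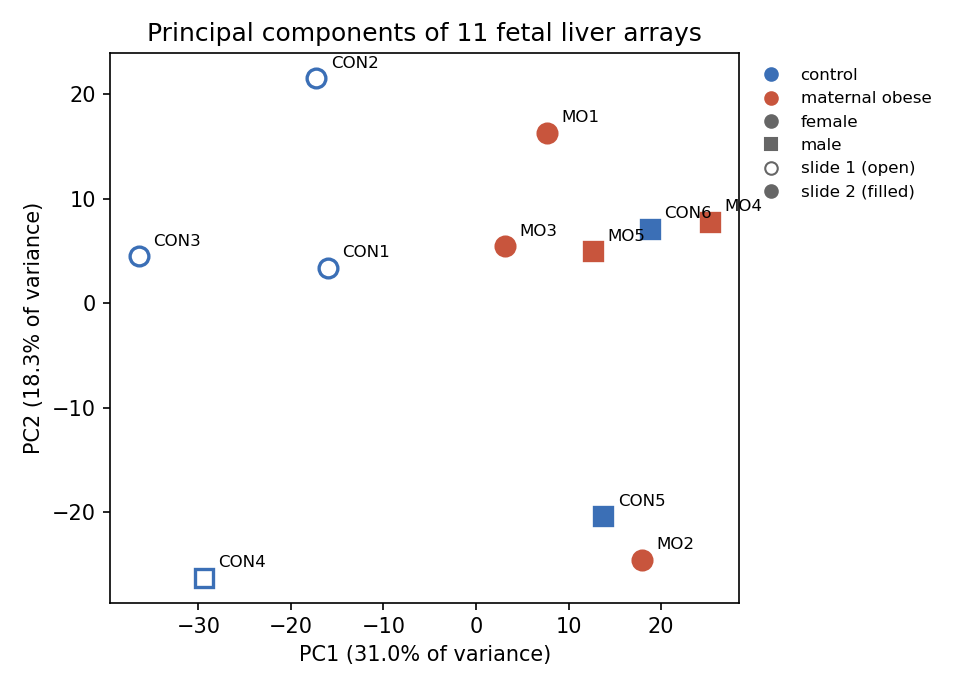
First against second principal component of the normalized log2 values, 1 point per array, with blue for control and red for maternal obese, circles for females and squares for males, and open points for slide 1 and filled points for slide 2. The 4 slide 1 arrays lie at -36.4 to -16.0 on the first component and the 7 slide 2 arrays at 3.13 to 25.3, with control and maternal obese arrays mixed on slide 2.

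The first question was how fetal liver expression differed between pregnancies of obese and control mothers at 0.9 of gestation. Genes of the TCA cycle and pyruvate dehydrogenase, which oxidise pyruvate and acetyl groups in mitochondria, fell as a list by 0.24 on the log2 scale in maternal obese livers, and 21 of the 22 measured members lay below 0 (camera adjusted p = 1.28e-04). With an estimated correlation the adjusted p = 0.159. Its members with the smallest p were IDH3B, a subunit of isocitrate dehydrogenase, at -0.60 (SE 0.21), SUCLA2, a subunit of succinyl-CoA ligase, at -0.64 (SE 0.22), the pyruvate dehydrogenase subunit PDHA1 at -0.73 (SE 0.31) and its dihydrolipoamide dehydrogenase DLD at -0.31 (SE 0.14). The list's scores were -0.27 to -0.08 in the 5 maternal obese livers and 0.02 to 0.27 in the 6 controls, without overlap (exact permutation p = 0.00216, the smallest of 462 splits, adjusted p = 0.0823 over 38 lists). As this permutation p can go no lower, a single list could not have passed after that adjustment. With slide as a covariate the list stood at -0.18 (adjusted p = 0.0363), while PDHA1 turned to 0.16, SUCLA2 went to -0.16, DLD to -0.13 and IDH3B to -1.0. SUCLA2 was detected on 4 of 6 control and 1 of 5 maternal obese arrays. With slide and sex as covariates (-0.15, adjusted p = 0.0779) and in the males of slide 2 alone (-0.15, 0.0706) it did not pass. Leaving out any 1 array left the list past the threshold.

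Markers of Kupffer cells and macrophages, the resident phagocytes of the liver, also fell as a list, by 0.26, with 19 of 20 members below 0 (camera adjusted p = 3.55e-04). The adjusted p = 0.741 with an estimated correlation, and the exact permutation test of the scores gave p = 0.158. CD74, the MHC class II invariant chain, stood at -0.43 (SE 0.15), the haemoglobin scavenger receptor CD163 at -0.60 (SE 0.27), lysozyme LYZ at -0.59 (SE 0.27) and the adhesion receptor SIGLEC1 at -0.47 (SE 0.23). The endotoxin co-receptor CD14 lay at -0.14 (SE 0.22) and CSF1R, the receptor of macrophage colony-stimulating factor, at -0.17 (SE 0.16). SIGLEC1 was detected on 5 of 6 control and 2 of 5 maternal obese arrays. With slide as a covariate the list stood at -0.32 (adjusted p = 0.00154), CD74 at -0.24, CD14 at -0.35 and CSF1R at -0.27. Within slide 2 this rests on CON6, whose score was 0.61 where that of CON5 was -0.25, and the exact permutation p there was 0.286. The call held without any 1 array, and without CON6 the list stood at -0.17 (adjusted p = 0.0457).

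Another 4 lists fell by camera at the preset correlation, and for each of them the adjusted p = 0.741 with an estimated correlation. Glycolysis stood at -0.28, with 11 of 14 members below 0 (adjusted p = 0.0210), among them the triosephosphate isomerase TPI1 at -0.66 (SE 0.25), the phosphofructokinase PFKM at -1.0 (SE 0.56), the phosphoglycerate kinase PGK1 at -0.36 (SE 0.21) and the aldolase ALDOA at -0.47 (SE 0.31). The urea cycle and amino acid catabolism list stood at -0.16, with 19 of 30 below 0 (adjusted p = 0.0191). Its glutaryl-CoA dehydrogenase GCDH lay at -0.50 (SE 0.20), the aspartate aminotransferase GOT1 at -0.45 (SE 0.19), the lysine-degrading AASS at -0.43 (SE 0.18) and the hydroxyproline dehydrogenase PRODH2 at 0.55 (SE 0.18). Oxidative phosphorylation stood at -0.12 with a median of -0.03 and 26 of 43 members below 0 (adjusted p = 0.0291). Its complex I subunits NDUFA3 and NDUFB5 lay at -0.86 (SE 0.25) and -0.98 (SE 0.41), the complex IV subunit COX6B1 at -0.51 (SE 0.18) and the complex III subunit UQCRH at -0.88 (SE 0.37). The proteasome list stood at -0.10, with 28 of 39 below 0 (adjusted p = 0.0108), and included PSMA2 at -0.58 (SE 0.21), PSMD14 at -0.29 (SE 0.13), PSMC1 at -0.26 (SE 0.12) and the activator subunit PSME2 at 0.30 (SE 0.15). Some members were not detected on every array: PFKM on 4 of 6 control and 1 of 5 maternal obese arrays, and TPI1 and AASS on 4 of 5 maternal obese arrays. With slide as a covariate, glycolysis (-0.47, adjusted p = 0.0312) and the proteasome (-0.12, adjusted p = 0.0312) still passed, and oxidative phosphorylation (-0.09, adjusted p = 0.102) and the urea cycle (-0.16, adjusted p = 0.127) did not. For glycolysis that fit rests on CON5, whose score was 0.68, while CON6 at -0.06 lay among the maternal obese livers (-0.31 to 0.10). Members moved in it too, with NDUFB5 at 0.26, UQCRH at 0.10, NDUFA3 and COX6B1 at -0.21 each, TPI1 at -0.28, PGK1 at -0.69, ALDOA at -0.93, PSMA2 at -0.13, GCDH at -0.88 and PRODH2 at 0.24. With slide and sex as covariates the proteasome (adjusted p = 0.0105) and the urea cycle (0.0492) passed, and glycolysis (0.193) and oxidative phosphorylation (0.170) did not. In the males of slide 2 only the proteasome passed (0.0390; glycolysis 0.157, oxidative phosphorylation 0.280, urea cycle 0.571), and with array weights none of the 4 did (0.105 to 0.358). Glycolysis was lost with median scaling too (0.0688), and with no filter (0.0761), detection on all arrays (0.141) or without CON3 and CON4 (0.0646). Oxidative phosphorylation was lost with no filter (0.0646) or without CON3 and CON4 (0.0915), and the urea cycle with detection on all arrays (0.174). Single arrays ended these calls as well. Without MO2 the shifts of oxidative phosphorylation (-0.0583, adjusted p = 0.530), the urea cycle (-0.0748, 0.324) and the proteasome (-0.0590, 0.140) shrank by over 1.5 times, and so did that of glycolysis without CON5 (-0.17, 0.159). The shift moved less where oxidative phosphorylation was lost without CON2 (-0.12, 0.0543), CON3 (-0.0873, 0.0921) or CON5 (-0.11, 0.185), glycolysis without MO1 (-0.25, 0.0547) or MO3 (-0.24, 0.0646), and the urea cycle without CON2 (-0.12, 0.0888), CON3 (-0.11, 0.0796) or CON6 (-0.14, 0.0515).

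In all, 6 of the 38 lists passed, all lower, and 0 passed with an estimated correlation or with fry (smallest adjusted p = 0.159 and 0.0502). Of 100 splits of the 11 arrays into 6 and 5, 54 called at least 6 lists, so the number of called lists does not stand apart from other groupings of these arrays. Of the 21 splits that keep slide 1 in the group of 6, 3 did, the real one among them, and the highest other one called 7. Of the 6 called lists, 0 members passed over all genes and 0 when adjusted over the list alone. The TCA cycle, oxidative phosphorylation, glycolysis, proteasome and Wnt lists name pathways that the study itself drew from these samples, so their counts are not independent evidence of direction.

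**Figure D2:**
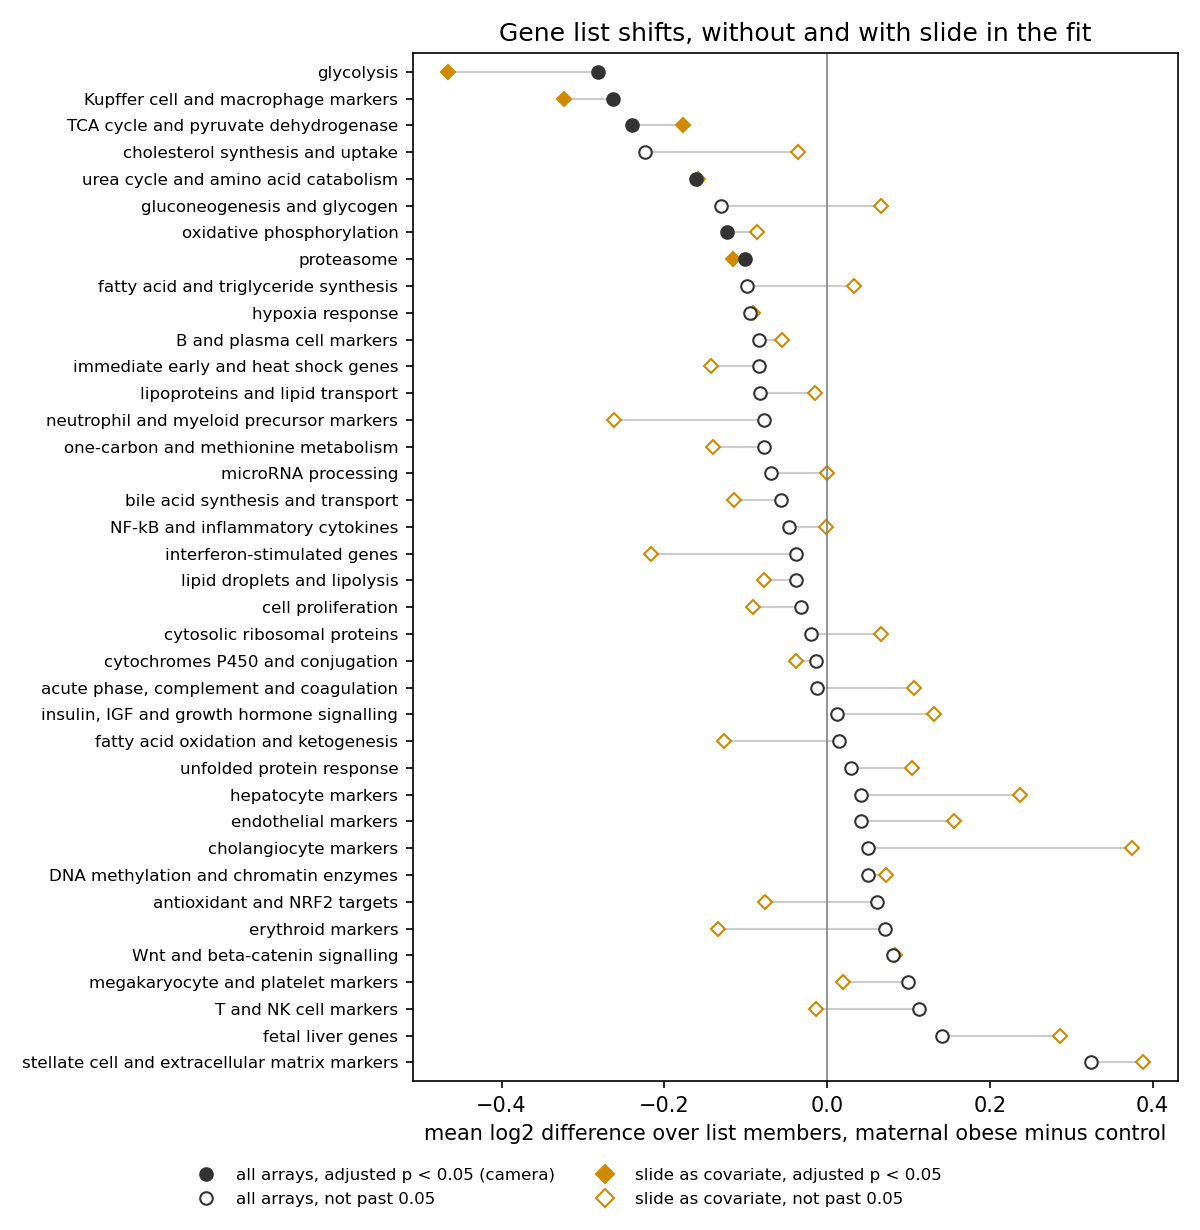
Mean log2 difference, maternal obese minus control, of each of the 38 gene lists, with all 11 arrays (black circles) and with slide as a covariate (orange diamonds), filled where the camera adjusted p is under 0.05. The 6 filled circles lie between -0.28 (glycolysis) and -0.10 (proteasome), and 4 of these lists are also filled with slide as a covariate.

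**Figure D3:**
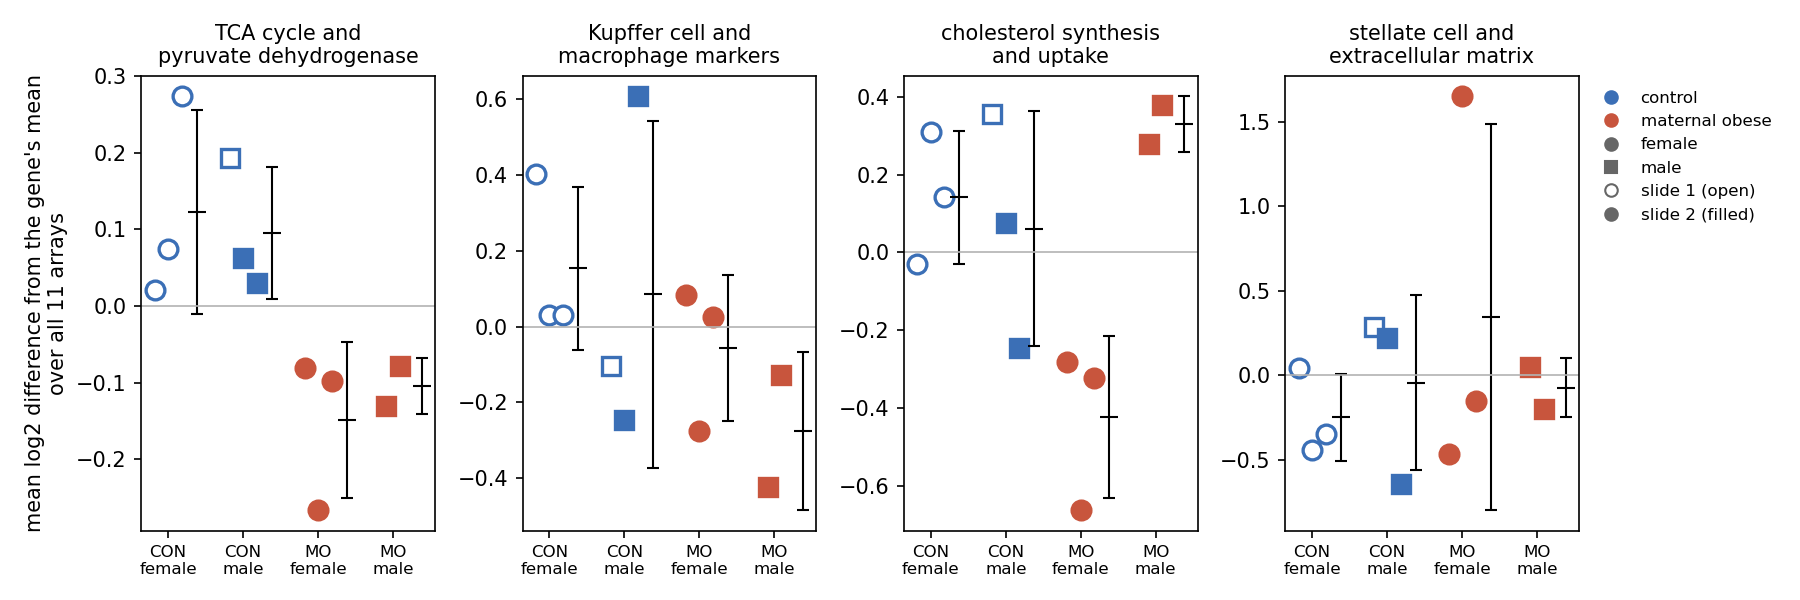
List scores per array (mean log2 difference of the members from their means over the 11 arrays) by condition and sex (circles female, squares male, open slide 1) for the TCA cycle, Kupffer cell, cholesterol synthesis and stellate cell lists, with group means and SD. TCA scores of the 5 maternal obese livers are -0.27 to -0.08 against 0.02 to 0.27 in controls, and cholesterol scores are -0.66 to -0.28 in maternal obese females and 0.28 to 0.38 in maternal obese males.

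Among single genes, MT1B, a metallothionein that binds zinc and copper, had the largest difference of the genes named here, at 9.09 ± 1.92 (SD, n = 6) in controls and 12.76 ± 0.47 (SD, n = 5) in maternal obese livers. This is 3.68 (SE 0.74), or 12.8-fold, with a limma adjusted p = 0.269. CON5 read 12.73 on this probe, like the maternal obese livers, and the other 5 controls 7.38 to 9.39. Without CON5 the difference of MT1B was 4.40 (limma adjusted p = 2.31e-04), and with slide as a covariate 1.95. Other genes with small p and higher means in maternal obese livers were the zinc finger gene ZNF160 at 1.06 (SE 0.18), FYCO1, an adaptor of autophagic vesicle transport, at 0.59 (SE 0.11), the Polycomb-associated ASXL2 at 1.06 (SE 0.20) and TNIP3, an inhibitor of NF-kB signalling, at 1.0 (SE 0.20). Lower means were found for the glutathione S-transferase GSTM5 at -1.31 (SE 0.25), MRFAP1L2 at -0.71 (SE 0.16), the methionine sulfoxide reductase MSRA at -0.65 (SE 0.16), the elongation factor kinase EEF2K at -0.81 (SE 0.19) and CEP15 at -0.80 (SE 0.19), which was detected on 5 of 6 control but only 1 of 5 maternal obese arrays. Slide as a covariate moved ZNF160 to 0.66, TNIP3 to 0.48, EEF2K to -0.27 and CEP15 to -0.46. By limma 0 of 10173 features passed, with a smallest adjusted p = 0.201, and 1314 had an unadjusted p under 0.05 (916 higher, 398 lower), where chance alone gives 508.65. With slide in the fit the 1314 became 787 (slide as covariate), 498 (slide as random block) or 500 (slide and sex as covariates). Within slide 2 alone the count was 845, and in its males 584. Without CON5 or without CON6, 1 feature passed. With slide as a covariate 1 gene passed, the growth arrest protein GAS2 at 1.62 (SE 0.19, limma adjusted p = 0.0192), which read 7.07 in CON5, 6.86 in CON6 and 7.93 to 8.95 on the other 9 arrays, and stood at 0.77 without the covariate.

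The other 32 lists did not pass, with camera adjusted p-values of 0.0633 to 0.995. In the gluconeogenesis and glycogen list (-0.13, adjusted p = 0.0633) the glucose-6-phosphate transporter SLC37A4 was lower, at -0.46 (SE 0.13), when adjusted over the list alone (limma adjusted p = 0.0438). IGF2R, the receptor that clears IGF2, was higher at 0.59 (SE 0.14) when adjusted over the insulin, IGF and growth hormone list alone (limma adjusted p = 0.0268), and that list stood at 0.01 (0.467). Of B and plasma cell markers (-0.08, 0.696), the B cell receptor component CD79B was lower at -0.74 (SE 0.20, limma adjusted p = 0.0206) and the B cell lectin CD22 higher at 0.40 (SE 0.14, limma adjusted p = 0.0385) when adjusted over the list alone. Slide as a covariate moved CD22 to 0.10. Over all genes tested these 4 genes did not pass. In the Wnt and beta-catenin list (0.08, 28 of 42 members above 0, adjusted p = 0.417) the Wnt receptors FZD5 and FZD1 lay at 0.56 (SE 0.16) and 0.45 (SE 0.15), and at 0.32 and 0.24 with slide in the fit. The list's fry adjusted p was 0.0502 and its exact permutation p 0.0152 (adjusted 0.288). In the list of DNA methylation and chromatin enzymes (0.05, 0.467) the histone methyltransferases SETD1B and KMT2C lay at 0.45 (SE 0.14) and 0.57 (SE 0.19).

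Stellate cell and extracellular matrix markers had a mean of 0.32 (adjusted p = 0.463), which rested on MO2. Its score was 1.65, against at most 0.29 on the other 10 arrays, and without it the list stood at -0.04 (adjusted p = 0.530). The collagen COL1A1 was at 1.15 (SE 0.63) and smooth muscle myosin MYH11 at 1.42 (SE 0.86), and 0.51 and 0.32 without MO2, while the collagen COL6A1 was at 0.67 (SE 0.29), the protease inhibitor TIMP1 at 0.84 (SE 0.43), the proteoglycan DCN at 0.38 and TGFBI at -0.07. MO2 was also the array whose absence ended the calls of oxidative phosphorylation, the proteasome and the urea cycle. Hepatocyte markers stood at 0.04 (0.644), with the plasma proteins TTR at 0.07 and ALB at -0.10. Slide as a covariate moved the list to 0.24 (0.0606), and within slide 2 alone it passed by camera (0.24, adjusted p = 0.0350), with an adjusted p = 0.782 with an estimated correlation and an exact permutation p of 0.0952. Among the other cell types, endothelial (0.04, 0.995), erythroid (0.07, 0.775), megakaryocyte (0.10, 0.775), neutrophil (-0.08, 0.619), T and NK cell (0.11, 0.619) and cholangiocyte markers (0.05, 0.649) did not pass.

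Lipid lists did not pass over all 11 arrays. Cholesterol synthesis and uptake stood at -0.22 (adjusted p = 0.114), fatty acid and triglyceride synthesis at -0.10 (0.467), lipoproteins and lipid transport at -0.08 (0.431), bile acid synthesis at -0.06 (0.467), lipid droplets and lipolysis at -0.04 (0.486) and fatty acid oxidation and ketogenesis at 0.01 (0.775). With slide as a covariate the cholesterol list went to -0.04. Slide and sex as covariates turned it to 0.29 (camera adjusted p = 0.0239) and fatty acid oxidation to -0.21 (0.0125). In the males of slide 2 cholesterol turned to 0.42 (0.00319) and fatty acid synthesis to 0.33 (0.00447). One-carbon metabolism stood at -0.08 (0.150), immediate early and heat shock genes at -0.08 (0.158), hypoxia genes at -0.09 (0.363), antioxidant and NRF2 targets at 0.06 (0.363), NF-kB and cytokine genes at -0.05 (0.434) and proliferation genes at -0.03 (0.463). Acute phase genes stood at -0.01 (0.463), cytochromes P450 at -0.01 (0.467), interferon-stimulated genes at -0.04 (0.467), microRNA processing at -0.07 (0.467), ribosomal proteins at -0.02 (0.467), fetal liver genes at 0.14 (0.525) and the unfolded protein response at 0.03 (0.696). The median over all features was 0.05. In 8 lists the mean lay above 0 and the camera direction below, as camera compares the moderated statistics of the members with those of all other genes (antioxidant, insulin and IGF, hepatocyte, cholangiocyte, unfolded protein response, fatty acid oxidation, erythroid and endothelial). In 6 lists the mean and the median differed in sign (bile acid, interferon, fatty acid synthesis, ribosomal, B cell and unfolded protein response).

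The next question was whether the difference was seen in fetuses of each sex. In females, 10 lists fell by camera at the preset correlation. With an estimated correlation all 10 were lost (adjusted p = 0.619 to 0.811), as they were with fry (0.321 to 0.837). Cholesterol synthesis and uptake had the largest shift, at -0.56 (camera adjusted p = 8.57e-05), followed by fatty acid and triglyceride synthesis at -0.40 (0.00941), the urea cycle at -0.31 (0.00154) and the TCA cycle at -0.27 (0.00154). Within them the acyl-CoA synthetase ACSL4 lay at -1.87 (SE 0.53). The squalene epoxidase SQLE, the lanosterol synthase LSS and the fatty acid elongase ELOVL6 were not detected on the 3 maternal obese female arrays, and were at least 3.24-fold, 2.15-fold and 1.59-fold higher in control females (limma adjusted p = 0.166, 0.204 and 0.281), with ELOVL6 detected on 2 of these 3. The others were Kupffer cell markers at -0.21 (0.0449), hepatocyte markers at -0.17 (0.0184), oxidative phosphorylation at -0.17 (0.0449), one-carbon metabolism at -0.15 (0.0449), acute phase genes at -0.13 (0.0272) and the proteasome at -0.10 (0.0449). Among control males, 1 on slide 1 and 2 on slide 2, the slides differed by -2.32 for SQLE, -1.30 for LSS and -1.02 for ELOVL6. All control females lay on slide 1 and all maternal obese females on slide 2, so these fold bounds cannot be told apart from slide. Slide can enter this contrast only through the males, of which 1 lay on slide 1, and then the cholesterol list stood at -0.12 (adjusted p = 0.737), the TCA list at -0.13 (0.737) and ACSL4 at -0.04. Of the 10 lists, the urea cycle (-0.62, adjusted p = 0.00183), one-carbon metabolism (-0.52, 0.00183) and Kupffer cell markers (-0.49, 0.0313) passed in that fit, with larger shifts, and the other 7 did not (0.156 to 0.737). In all 8 lists passed in it, 5 lower and 3 higher, the higher ones being stellate cell (1.09), cholangiocyte (1.17) and insulin and IGF genes (0.29). With array weights only the cholesterol and TCA cycle lists passed. Detection on all arrays ended the calls of oxidative phosphorylation (0.0592) and one-carbon metabolism (0.184), and leaving out CON3 and CON4 those of oxidative phosphorylation (0.444), the proteasome (0.278) and one-carbon metabolism (0.0967). Single arrays ended calls as well. Without MO2 only the cholesterol and TCA cycle lists passed, without CON2 4 lists and without CON4, a male that enters only the shared spread, 6. Cholesterol and the TCA cycle passed without any 1 array. The fatty acid list was lost without CON2 (-0.20, adjusted p = 0.0754), and at a similar shift without MO2 (-0.35, 0.0841). Without MO2 most of the others shrank by over 1.5 times: the urea cycle (-0.15, 0.113), hepatocyte markers (-0.0637, 0.174), acute phase genes (-0.00718, 0.653), Kupffer cell markers (-0.0999, 0.345), oxidative phosphorylation (-0.0499, 0.721), one-carbon metabolism (-0.0753, 0.263) and the proteasome (-0.00985, 0.653). So did Kupffer cell markers without CON1 (-0.0859, 0.359), and oxidative phosphorylation (-0.0934, 0.511) and the proteasome (-0.0626, 0.295) without CON3. Other losses came with about the same shift. Without CON2 these were hepatocyte markers (-0.15), acute phase genes (-0.12), oxidative phosphorylation (-0.17), one-carbon metabolism (-0.16) and the proteasome (-0.0943), with an adjusted p = 0.0633 each, and without CON3 one-carbon metabolism (-0.15, 0.0851). Leaving out a male cannot move the female shift, and ended the calls of Kupffer cell markers (0.0581), oxidative phosphorylation, one-carbon metabolism and the proteasome (0.0578 each) without CON4, and of the proteasome without CON5 (0.0516), MO4 or MO5 (0.0534 each). Without MO1 the proteasome stood at -0.18 and acute phase genes at -0.20, and hepatocyte markers at -0.29 without CON1 and -0.08 without CON3.

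Among single genes in females, the progestin receptor PAQR7 lay at -1.88 (SE 0.25), GSTM5 at -1.72 (SE 0.24), the leukocyte integrin ITGB2 at -1.22 (SE 0.19), HSD17B2, which oxidises oestradiol and testosterone, at -1.03 and the cap-binding protein NCBP2 at -1.39 (SE 0.24). Positive differences were those of MT1B at 4.52 (SE 0.98), ANKRD26 at 0.86 (SE 0.14), FYCO1 at 0.72 (SE 0.14) and REPIN1 at 0.71 (SE 0.16). KCTD7, a potassium channel tetramerisation domain protein, was not detected on the 3 control female arrays and was at least 1.38-fold higher in the 3 maternal obese ones (limma adjusted p = 0.152). Of the 3 maternal obese female arrays, PAQR7 was detected on 1 and ITGB2 on 2. Among control males, 1 on slide 1 and 2 on slide 2, the slides differed by -0.41 for ITGB2, -0.26 for HSD17B2 and -0.90 for NCBP2. For PAQR7 (0.24) and GSTM5 (0.36) the slide difference ran against the female one. For the genes with positive female differences it ran the same way, with MT1B at 2.93. With slide in the female contrast, ITGB2 went to -0.81, HSD17B2 to -0.77, NCBP2 to -0.49, MT1B to 1.59 and REPIN1 to 0.40. By limma 0 genes passed, with a smallest adjusted p = 0.0525 (PAQR7 and GSTM5), 7 with an adjusted p under 0.1 and 1335 with an unadjusted p under 0.05 (585 higher, 750 lower). The count depended on the spread of the males in the shared fit. Without CON4, 294 genes passed, without CON6 4, and without CON1 or CON5 1 each.

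In males, Kupffer cell markers fell by 0.36 (camera adjusted p = 8.73e-04) and the TCA cycle list by 0.20 (0.0233). With an estimated correlation the adjusted p = 0.701 for both lists, and with fry 0.884 and 0.486. The Kupffer cell list was lost without CON6 (-0.0996, adjusted p = 0.315) or MO4 (-0.21, 0.0571), and the TCA cycle list, at similar shifts, without CON4 (-0.15, 0.0808), MO4 (-0.17, 0.0571) or MO5 (-0.23, 0.0910). The TCA cycle list was also lost with slide as a covariate (0.0808) and without CON3 and CON4 (0.0737), and the Kupffer cell list with array weights (0.0992). Without CON4 4 lists passed, and without MO4 1. Among single genes the nuclear factor partner NFATC2IP lay at 1.01 (SE 0.19), the hexokinase domain gene HKDC1 at 1.65 (SE 0.31), the transcription factor SALL2 at 0.98 (SE 0.20), GAS2 at 1.39 (SE 0.29) and ASXL2 at 1.39 (SE 0.29). Negative differences were those of the antiviral TRIM22 at -1.19 (SE 0.21), the glucuronosyltransferases UGT1A7 at -2.18 (SE 0.41) and UGT1A10 at -2.39 (SE 0.46), whose probes share sequence, CACYBP (detected on 1 of the 2 maternal obese males) at -1.34 (SE 0.26) and AAMDC at -1.45 (SE 0.31). By limma 0 genes passed (smallest adjusted p = 0.311) and 909 had an unadjusted p under 0.05 (519 higher, 390 lower), with 2 maternal obese against 3 control arrays. Without MO5 4 genes passed and without MO4 1.

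Whether the difference depended on fetal sex was tested as an interaction. Cholesterol synthesis and uptake stood at -0.56 in females and 0.27 in males, a difference of -0.83 (camera adjusted p = 2.21e-06), and fatty acid and triglyceride synthesis at -0.40 and 0.30, a difference of -0.69 (8.03e-05). Hepatocyte markers (-0.17 and 0.26, difference -0.43, 9.47e-04) and acute phase genes (-0.13 and 0.10, difference -0.22, 0.0218) made up the 4 lists called. With an estimated correlation the adjusted p was 0.388 for the cholesterol, fatty acid and hepatocyte interactions and 1.0 for the acute phase one, so all 4 calls depend on the preset correlation. In males the cholesterol and fatty acid lists did not pass on their own (adjusted p = 0.0656 each). The sterol reductase DHCR7 lay at -1.25 in females and 0.84 in males, a difference of -2.09 (SE 0.35). The farnesyl diphosphate synthase FDPS lay at -1.04 and 0.81 (difference -1.85, SE 0.38), and the intestinal and hepatic sterol transporter NPC1L1 at -0.46 and 0.86 (difference -1.32, SE 0.26). ACSL4 differed by -1.97, and by -0.76 with slide in the fit. Other members lay nearer in the sexes, with the sterol oxidase MSMO1 at -0.94 in females and -0.86 in males, the thiolase ACAT2 at -0.11 and -0.39, the lipogenic transcription factor MLXIPL at 0.31 and 0.37 and the acyltransferase GPAT3 at -0.27 and -0.64. With slide in the fit MSMO1 stood at 0.38 and -0.42, and MLXIPL at -0.45 and 0.11.

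Exact permutation tests of the scores of the cholesterol, fatty acid, hepatocyte and acute phase lists gave p = 0.06, 0.025, 0.1 and 0.235, none past the threshold after adjustment over 38 lists. The permutation p can go no lower than 0.005 here, so a single list could not have passed after that adjustment. Slide can enter the interaction fit only through the control males, with CON4 on slide 1 against CON5 and CON6 on slide 2. CON4 also carried XIST, as given below. With slide as a covariate the cholesterol interaction stood at -0.54 (adjusted p = 0.0323) and the fatty acid one at -0.64 (0.0125), and the hepatocyte (0.162) and acute phase (0.276) calls were lost. The acute phase call was also lost without MO2 (-0.10, 0.434), and at a similar shift without CON3 (-0.22, 0.0717), CON5 (-0.20, 0.0823) or MO5 (-0.24, 0.0652). Without CON1 or CON6 9 lists passed, and without MO1 7. Among the males of slide 2 alone the cholesterol list stood at 0.42 (adjusted p = 0.00319) and the fatty acid list at 0.33 (0.00447), with an adjusted p = 0.911 for both with an estimated correlation. Scaling to a common median moved the median of all features in males to -0.24, and the cholesterol list to -0.07 and the fatty acid list to -0.03, below 0 but above that median.

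Outside these lists, PAQR7 lay at -1.88 in females and 0.18 in males (difference -2.06, SE 0.38) and HSD17B2 at -1.03 and 0.28 (difference -1.32, SE 0.26), and GLYAT, the mitochondrial glycine acyltransferase, lay at 0.97 in females and -1.60 in males (difference 2.57, SE 0.48). The farnesyltransferase subunit FNTA (1.10, SE 0.21), TMED4 (1.38, SE 0.28), TMEM69 (1.25, SE 0.26) and DDN (0.90, SE 0.21) had positive interactions too. By limma 0 interactions passed (smallest adjusted p = 0.303, DHCR7) and 741 had an unadjusted p under 0.05 (311 higher, 430 lower). Without CON4 14 genes passed, and without MO4 or MO5 1 each.

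Female and male livers differed in the transcripts that mark sex. XIST, the RNA that silences an X chromosome, was 8.78 ± 0.26 (SD, n = 6) in females and 5.41 ± 1.08 (SD, n = 5) in males, a difference of 3.42 (SE 0.38, limma adjusted p = 0.00390). The Y-linked ribosomal protein genes RPS4Y1 and RPS4Y2 differed by -5.49 (SE 0.51, limma adjusted p = 7.13e-04) and -5.14 (SE 0.20, limma adjusted p = 5.00e-08), and their probes may bind either transcript. CON3, a female, read 7.85 on RPS4Y1, where the other females read 4.87 to 5.51, and CON4, a male, read 7.35 on XIST, where the other males read 4.89 to 4.97. Probes of the other Y-linked genes (DDX3Y, EIF1AY, USP9Y, UTY, ZFY, TMSB4Y) were detected on 0 arrays, and KDM5D on 2 female ones.

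**Figure D4:**
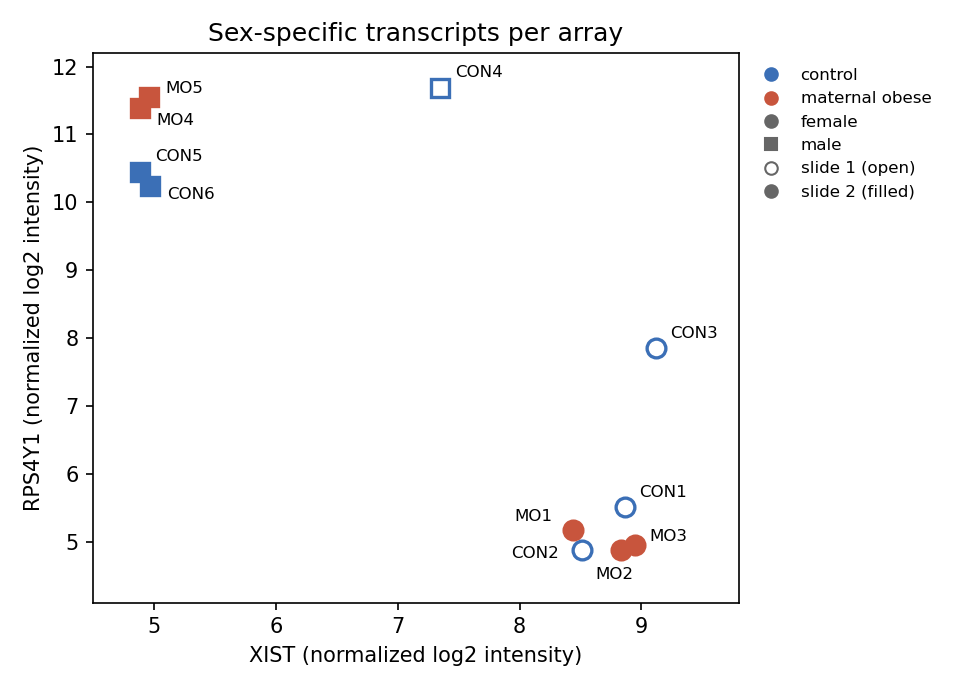
Normalized log2 intensity of XIST (x axis) against RPS4Y1 (y axis), 1 point per array, with blue for control and red for maternal obese, circles for females and squares for males, and open points for slide 1. CON4, a male, lies at 7.35 on XIST, above the other males (4.89 to 4.97), and CON3, a female, at 7.85 on RPS4Y1, above the other females (4.87 to 5.51).

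The X-linked phosphatase DUSP9, detected on 4 of 6 female arrays, was lower in females, at -1.34 (SE 0.20, limma adjusted p = 0.0417), and with 1 probe without a gene symbol (0.89) completed the 5 features past the threshold. DUSP9 did not pass without CON1 (adjusted p = 0.152), CON2 (0.171), CON3 (0.0957), CON4 (0.0592), MO1 (0.144), MO2 (0.0815), MO3 (0.108), MO4 (0.177) or MO5 (0.125), nor with slide as a covariate (-1.20, adjusted p = 0.365), where the sex hormone-binding globulin SHBG passed instead (1.35, adjusted p = 0.0300). Without the covariate, below the threshold, SHBG lay at 1.09 (SE 0.19), GSG1L at 1.01 (SE 0.17), the GTPase RRAGB at 1.11 (SE 0.20), the gap junction protein GJA4 at 0.83 (SE 0.15) and HNRNPL at -0.51 (SE 0.11), with GSG1L detected on 3 and RRAGB on 2 of the 5 male arrays, and CD99 lay lower in females with an adjusted p = 0.235. The count fell to 3 without CON1, CON2, CON3, MO3 or MO5.

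Among lists, acute phase genes (0.17, camera adjusted p = 0.0173) and endothelial markers (0.21, 0.0173) were higher and cholesterol synthesis (-0.29, 0.0305) lower in females, each with an adjusted p = 0.966 with an estimated correlation. In maternal obese livers, all on slide 2, the mean cholesterol scores were -0.42 in females and 0.33 in males. In controls these were 0.14 and 0.06, but there sex mixes with slide. On slide 1 the control females scored -0.03 to 0.31 and the only male, CON4, 0.36. The control males of slide 2 scored 0.07 (CON5) and -0.25 (CON6). Without CON4 0 lists passed, as acute phase genes (0.15, adjusted p = 0.0775), endothelial markers (0.22, 0.0775) and cholesterol synthesis (-0.26, 0.235) were all lost. Endothelial markers were also lost without CON1 (0.16, 0.0608) or MO4 (0.15, 0.207), and cholesterol synthesis without MO2 (-0.20, 0.151), MO3 (-0.27, 0.0609), MO4 (-0.21, 0.207) or MO5 (-0.18, 0.253). Slide as a covariate ended the call of acute phase genes (0.14, 0.113), and cholesterol synthesis (-0.55, 1.30e-09) and endothelial markers (0.20, 0.0240) passed. No filter ended the calls of cholesterol synthesis (0.0766) and endothelial markers (0.0678), detection on all arrays that of endothelial markers (0.249), and leaving out CON3 and CON4 those of cholesterol synthesis (0.182) and acute phase genes (0.107). Without CON1 6 lists passed, and without CON2 or CON6 5.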

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

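Of the tests below, those of slide and of hepatocyte share for the TCA cycle list, both slide tests for the cholesterol list and the test of swapped labels were chosen after their values were seen. The cholesterol slide tests replaced an earlier one that was judged unsuitable once seen. The comparison of mixing with other pairs of arrays, the fits without CON3 and CON4 and the list tests of the interaction, with all their alternatives, were chosen after the data were seen too. So were the splits within slide 2 and the use of the spread between arrays for hepatocyte markers. The other tests were fixed beforehand.

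In 266 sets of 5 or 6 arrays, 15 held 1 array far from the rest, where chance gives about 1 in 20, or 13.3. MO2 stood apart on MYH11 (12.43, the other maternal obese arrays 6.56 to 7.13), PFKM (6.47, others 5.08 to 5.44), the stellate cell score (1.65, others -0.46 to 0.05) and the TCA cycle score (-0.27, others -0.13 to -0.08). MO4 stood apart on NCBP2 (6.55, others 6.18 to 6.28) and TTR (14.55, others 14.67 to 14.69), MO5 on ACAT2 (11.14, others 10.50 to 10.68) and MO1 on the Wnt score (-0.0264, others 0.05 to 0.08). Among controls, CON4 stood apart on KMT2C (5.39, others 6.16 to 6.45) and CON2 on the fatty acid synthesis score (0.53, others -0.15 to 0.05). Among females CON2 stood apart on GSG1L (6.97, others 6.31 to 6.54), and among males MO4 on GJA4 (6.65, others 6.08 to 6.17). The sex transcripts that stood apart were XIST in CON4 (7.35, other males 4.89 to 4.97) and RPS4Y1 and RPS4Y2 in CON3 (7.85 and 6.05, other females 4.87 to 5.51 and 4.96 to 5.33).

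The TCA cycle list was lower in maternal obese livers, by a mean of -0.24, with p = 0.00216 in the exact permutation test of its scores (adjusted p = 0.0823 over 38 lists). If slide were the whole cause, no difference would remain within slide 2. There it was -0.18, with all 5 maternal obese scores below both control scores (exact permutation p = 0.0476, the smallest of 21 splits). The scores of all 11 arrays did not overlap, so this separation and its p were given once the list was picked. The insulin and IGF list and the fetal liver list had the same exact permutation p within slide 2. The separation therefore cannot decide whether slide is the whole cause. Both controls there are male and the maternal obese livers of either sex, with -0.15 among the males alone. The study drew this pathway from these same samples, and the test was chosen after its values were seen, so the p is not independent evidence. Slide stays open, as the whole cause or a part of it. Control males differed by -0.15 between the slides (1 on slide 1, 2 on slide 2). The list did not pass with slide and sex in the fit (-0.15, camera adjusted p = 0.0779). A smaller share of hepatocytes would lower their markers by about as much. Within slide 2 these stood at 0.24 (SE 0.111), above a bound of -0.0887 set midway between no change and the TCA difference there. That argues against a smaller share there, though with 2 control males only (exact permutation p = 0.0952 for no difference). Over all 11 arrays the markers' median difference of 0.0173 cannot be told apart from the like bound of -0.12 (SE 0.123). In females, compared across slides, the markers stood at -0.17 and the TCA list at -0.27, so a smaller share stays open there. In males they stood at 0.26 and -0.20. Maternal obesity stays open as a hypothesis, and so does an unrecorded difference between the fetuses.

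By camera at the preset correlation the cholesterol synthesis list differed between the sexes (interaction -0.83), as did fatty acid and triglyceride synthesis (-0.69), hepatocyte markers (-0.43) and acute phase genes (-0.22), but all 4 calls were lost with an estimated correlation (adjusted p = 0.388 to 1.0), and the exact permutation p of cholesterol was 0.06. Without CON3 and CON4, which carry transcripts of the other sex, the cholesterol interaction was -0.98 and still passed at the preset correlation (camera adjusted p = 5.89e-06). The call thus does not need these arrays. CON4 is the only male of slide 1, however, so in this fit the interaction cannot be told apart from slide. In females slide cannot be told apart from maternal obesity, as the groups lay on different slides and the difference went from -0.56 to -0.12 with slide in the fit, estimated from 1 male of slide 1. Within slide 2 both maternal obese males lay above both control males, but the gap of 0.20 was smaller than the range of 0.32 within a group, so 2 against 2 arrays leave the males open too. A sex-specific response of sterol synthesis may underlie the pattern and stays untested.

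CON3 and CON4, both on slide 1, each carried a transcript of the other sex. A swap of their labels is argued against, because the RPS4Y1 intensity of CON3 was 0.203 of the lowest male intensity and the XIST intensity of CON4 lay below that of every female. Mixing of RNA between the pair could account for both readings, at 26.7% of CON3's XIST in CON4 and 6.63% of CON4's RPS4Y1 in CON3, and would forbid abundant genes far below those shares. Only 1 of 1226 genes in CON4 and 0 of 432 in CON3 lay that low, but 28.7% and 61.1% of the other ordered pairs of arrays had no more, so the test has no power and mixing cannot be told apart from other sources. No biological explanation was tested.

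For female against male, 1 of 99 splits, the real one, gave as many genes (5 genes, highest other 2). XIST, RPS4Y1 and RPS4Y2, which mark sex itself, are among the 5, so this outcome mainly checks the sex labels. It cannot exclude chance for DUSP9 on its own. For the number of called lists between maternal obese and control livers chance stays open, since 54 of 100 splits gave at least as many (6 in the real split, 17 in the highest other one), as did 3 of the 21 that keep slide 1 in the group of 6 (highest other 7). For genes the real count was 0, which every split reaches (100 of 100, highest other 13, and 426 in the highest of those 21), so this count says nothing about chance. The same holds in females, where 10 of 10 splits reach the real count of 0 and the highest other one called 1.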

How the results depend on the processing

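The list tests other than in maternal obese against control, their alternatives, and the fits without CON3 and CON4, were chosen after seeing the data. Of 7193 alternative values over 124 gene results and 38 lists in 5 comparisons, 6803 stayed on their side of the threshold without a called reversal (602 of them changed sign uncalled), 174 were no longer past it, 190 newly passed and 26 reversed. Most of these values belong to results that did not pass to begin with, so they do not measure how stable the calls are. Each list called in maternal obese against control had 27 alternatives. Kupffer cell markers passed in 25 of them, the TCA cycle in 23, the proteasome in 23, the urea cycle in 16, glycolysis in 15 and oxidative phosphorylation in 14. Limits come from 11 arrays with 20.8% to 26.8% of probes detected and from slide. The cause was not tested unless stated. No paired analysis was possible because the labels give no numbers that pair the arrays. Testing all probes separately was not run for lists.

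With an estimated correlation and with fry, 0 lists passed in each of the 5 comparisons. Maternal obese against control called 1 gene with the series matrix, 1 with slide and 1 with sex as covariate, and 7 with array weights, and leaving out 1 array gave 0 to 1. Its lists went from 6 to 11 with the series matrix and 2 with array weights, and 4 to 8 without 1 array. In females the genes went from 0 to 5 without background correction, 1 with the series matrix, 1 with no filter, 3 when detected on all arrays (fewer genes tested), 223 with array weights (53 higher, 170 lower), 7 with a trended robust prior and 13 without CON3 and CON4, and 0 to 294 without 1 array, and the lists from 10 to 2 with array weights and 2 to 14 without 1 array. In males the genes went to 1 with the series matrix and 2 with array weights, and 0 to 4 without 1 array, and the lists from 2 to 7 with median scaling, 8 with the series matrix, 4 with no filter, 4 with slide and 8 with array weights, and 1 to 4 without 1 array. Interactions of genes went to 1 with the series matrix and 2 without CON3 and CON4, and 0 to 14 without 1 array, and of lists from 4 to 7 with the series matrix, and 3 to 9 without 1 array. Female against male went from 5 genes to 3 without background correction, with median scaling, with the series matrix and without CON3 and CON4, 2 with no filter (XIST lost, adjusted p = 0.117), 0 when detected on all arrays (these transcripts are not tested there), and 3 to 5 without 1 array. Its lists went from 3 to 6 with median scaling, 10 with the series matrix, 6 with slide, 1 without CON3 and CON4, and 0 to 6 without 1 array.

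Reversed in all arrays were, in the males of slide 2, fatty acid synthesis (0.33), cholesterol synthesis (0.42) and erythroid markers (-0.25), and with slide and sex as covariates fatty acid oxidation (-0.21) and cholesterol synthesis (0.29). In females, slide reversed fatty acid oxidation (-0.37). The other reversals follow normalizations that move the median of all features, so they are set beside it. The median moved to -0.13 with median scaling in all arrays. With the series matrix in females it was 0.24, and gluconeogenesis (0.00256), proteasome (0.0394), bile acid (0.0165), one-carbon (0.0076) and ribosomal (0.0368) lists lay above 0 but below it. In males it was -0.24 with median scaling, with fatty acid (-0.0331), cholesterol (-0.0742), fetal liver (-0.0677) and hepatocyte (-0.0234) lists above it, and -0.16 with the series matrix, with fatty acid (-0.00987), cholesterol (-0.0706) and fetal liver (-0.0423) lists above it. For the interaction it was 0.25 with median scaling (lipoproteins 0.0157) and 0.39 with the series matrix (lipoproteins 0.17, urea cycle 0.17, acute phase 0.18, fetal liver 0.20). For female against male it was -0.16 with the series matrix (fatty acid oxidation -0.0331, urea cycle -0.0400, stellate -0.0523). The split of unadjusted calls moved likewise, from 916 higher and 398 lower in all arrays to 203 and 1017 with median scaling and 241 and 320 with the series matrix, from 585 and 750 in females to 1868 and 245 with the series matrix, from 519 and 390 in males to 46 and 1204 and to 25 and 1043, from 311 and 430 for the interaction to 694 and 80 and to 1691 and 35, and from 745 and 358 for female against male to 178 and 544 with the series matrix.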

Other observations

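The males of slide 2, 2 maternal obese and 2 control, are the only fetuses of 1 sex that can be compared within a slide, and 7 lists passed camera there at the preset correlation. With an estimated correlation the adjusted p was 0.911 to 0.924 for all 7. Hepatocyte markers stood at 0.26 (camera adjusted p = 0.0246) and fetal liver genes, a list that includes AFP and IGF2, at 0.39 (0.0384), together with cholesterol synthesis at 0.42 (0.00319) and fatty acid synthesis at 0.33 (0.00447). Kupffer cell markers stood at -0.45 (1.05e-04). This rests on CON6, whose score was 0.61, as CON5 at -0.25 lay below MO5 at -0.13, and without CON6 the difference in all males was -0.10 (0.315). Erythroid markers stood at -0.25 (0.0415), which rests on CON5 at 0.50, as CON6 at -0.15 lay below MO4 (-0.02) and MO5 (-0.13). Without CON5 the difference in all males was 0.04. The proteasome stood at -0.13 (0.0390). By limma 0 genes passed, with 584 at an unadjusted p under 0.05. Over all 11 arrays hepatocyte (0.04), fetal liver (0.14) and erythroid (0.07) lists did not pass.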
